A study of Homo sapiens with 6 samples.

How the data were processed

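The series holds RNA sequencing of 6 libraries in 3 groups of 2: cells with a negative control guide, cells with a guide against the variant site rs28684409, and cells whose titles give a shortened number, read here as the site rs179785 because the protocols name no other target ending in those digits. In CRISPR interference (CRISPRi) a guide RNA brings an inactive Cas9 to a site in order to repress it. The titles and the cell line tag name 786-O, a line from a clear cell renal cell carcinoma, while the source name of every sample reads 769P, another renal carcinoma line, so the labels disagree about the line. Guides were delivered by lentivirus and cells were selected with puromycin at 2 µg/ml, per the labels' protocols.

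The authors deposited 2 tables of 28099 gene symbols each. One holds estimated counts per gene, as deposited by the authors. The submitters' processing notes name Salmon, DESeq2 and the build hg38, without the step each was used for. The other holds TPM values per gene (abundance corrected for transcript length and scaled to the same total in each library), as deposited by the authors. Versions, the annotation and the way transcripts were summed to genes are not given in the sources used here. The estimated counts in the deposited table are not whole for 65.9% and 64.0% of symbols in the 2 control libraries. For the 17238 symbols above 0 in both libraries, the estimated count per TPM differed between the libraries by 1 factor, 1.37, and no symbol departed from it by more than 1.8e-09 on the log2 scale. The counts are therefore TPM values multiplied by a constant of each gene and a constant of each library, and hold no information on transcript length in a single library.

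The 2 control libraries were matched to columns named with NC and a number, which fit the negative control guide of the protocol and the replicate numbers of the titles. Another 4 columns of each table, 8 in all, carry names that match no title or other label, and column order and values were not used to assign them. They were not analysed here. The 3 comparisons fixed before the data were examined (each target site against the control guide, and the sites against each other) need those columns, so none of the tests fixed for them was run, and neither were gene set tests or the overlap of calls. What follows describes the 2 control libraries, the background against which the targeted cells would be read.

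Levels are the deposited TPM values, as mean ± SD over 2 libraries. The labels do not say that replicates came from separate cultures, so the SD may be technical. No test between groups was run, since the columns of the targeted cells could not be matched, so no p-value is given. A difference between genes is described only against the spread between the libraries. That spread does not cover measurement bias that differs between genes, so it cannot rank genes at similar levels. The 34 gene lists were fixed before the data were examined, as were 7 genes to be named whatever their values (KCNQ1, CDKN1C, VHL, EPAS1, CCND1, PAX8 and VEGFA). The rest of the fixed rule needs test results. All other named genes were picked with their values in view, as high, low or well-known members of their list, and are examples rather than a selection by rule. Some genes of the lists are not reported here by name. A gene counted as detected at 1 TPM or more in both libraries. The libraries were compared by log2 ratios of CPM (estimated counts scaled to the same total in each library) with a pseudocount of 0.5, over genes with a mean estimated count of at least 50, and by correlation of log2(TPM + 1). An exact 0 can be a failed estimate and is given as listed at 0, with no upper limit, since the deposited counts are not numbers of reads.

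The thresholds of detection, of the mean count and of 2-fold were also set after the data were seen, as were the classes of genes used to describe what differed between the libraries. The total estimated count was 28552055 in control replicate 1 and 20343207 in control replicate 2. The comparison of the 2 libraries was tested on simulated data over 12420 genes: of 200 genes changed 4-fold in whole counts drawn with a dispersion of 0.01, 97.5% were found at 2-fold or more and 1 unchanged gene was called. Gene positions are from GENCODE release 29 on GRCh38, the assembly that hg38 names. Annotated lengths are genomic spans from the RefSeq gene table, which matched 26824 symbols. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.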

Results

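RNA was sequenced from CRISPRi cells of a renal carcinoma line carrying either a negative control guide or a guide against one of the variant sites rs28684409 and rs179785, with 2 libraries in each of 3 groups. The design compares expression in cells with a targeted site with that in control cells. The 4 columns of each table that could belong to the targeted cells matched no label by name, so no comparison of targeted with control cells was made, and the results describe control replicates 1 and 2. Their total estimated counts were 28552055 and 20343207. The 10 genes with the highest estimated counts, which are not corrected for transcript length, took 6.42% and 6.69% of these, led by FN1, which encodes fibronectin, in both libraries. Of 28099 symbols, 13023 reached 1 TPM in both control libraries.

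The 7 genes fixed for naming spanned a wide range of levels in the control cells. EPAS1, which encodes HIF-2α (chromosome 2, 46293667 to 46386703, GRCh38), stood at 109.6 ± 1.06 TPM (SD, n = 2). VHL, whose product marks HIF-α subunits for degradation (chromosome 3, 10141008 to 10152220), stood at 40.6 ± 0.0212 TPM. CCND1, encoding cyclin D1 (chromosome 11, 69641087 to 69654474), was at 236.7 ± 2.14 TPM, and VEGFA, the angiogenic growth factor (chromosome 6, 43770184 to 43786487), at 338.8 ± 0.912 TPM. PAX8, a kidney lineage transcription factor (chromosome 2, 113215997 to 113278950), was at 120.9 ± 6.53 TPM. CDKN1C, a cyclin-dependent kinase inhibitor (chromosome 11, 2883213 to 2885773), was at 13.6 ± 1.51 TPM. KCNQ1, a potassium channel gene (chromosome 11, 2444684 to 2849110), was listed at 0 in both libraries. All 7 are annotated as protein-coding genes.

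Hypoxia-inducible factor (HIF) targets were widely expressed in the control cells. Of 27 members, 26 reached 1 TPM in both libraries, with a list median of 46.7 TPM. The glucose transporter SLC2A1 was highest at 638.3 ± 11.2 TPM (n = 2), followed by NDRG1 at 405.6 ± 17.8 TPM. The lipid droplet coat gene PLIN2 was at 209.8 ± 1.64 TPM. The carbonic anhydrases differed from each other by far more than the spread between libraries, CA12 at 72.6 ± 1.81 TPM and CA9 at 1.68 ± 0.336 TPM. Among VHL, HIF subunits and hydroxylases, 13 of 14 were detected (list median 36.2 TPM), with HIF1A at 94.8 ± 1.60 TPM and EGLN3 at 31.9 ± 0.546 TPM. HIF3A was not detected at 1 TPM (0.0424 and 0 TPM). Of 17 glycolytic genes 17 were detected (median 333.2 TPM), led by GAPDH at 8434 ± 4.23 TPM, ENO1 at 5979 ± 29.3 TPM and PKM at 4544 ± 81.0 TPM. The HK2 level was 14.6 ± 0.0504 TPM against 109.3 ± 0.455 TPM for HK1. All 31 nuclear-encoded respiratory chain genes were detected, with a median of 146.5 TPM. The 13 mitochondrially encoded genes of a further list were not analysed here.

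Most kidney lineage factors were detected and most proximal tubule markers were under 1 TPM. Of 15 lineage factors 12 were detected (median 18.2 TPM), with HOXA9 at 59.0 ± 4.60 TPM and PAX2 at 13.9 ± 1.12 TPM, while EYA1, SIM2 and EMX2 were listed at 0. Of 28 proximal tubule markers 8 were detected and the list median was 0.188 TPM, or 58.5 TPM over the detected members. HAVCR1, the injury marker KIM-1, was highest at 140.6 ± 5.87 TPM, followed by the brush border enzymes ANPEP at 85.2 ± 0.596 TPM and GGT1 at 73.0 ± 2.38 TPM. The megalin gene LRP2 was at 0.00405 and 0 TPM, and the anion transporter SLC22A6 was listed at 0.

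Genes of both epithelial and mesenchymal type were present. The keratin genes KRT8 and KRT18 were at 1428 ± 7.46 and 555.2 ± 8.17 TPM (n = 2), whereas CDH1, encoding E-cadherin, was at 0.248 and 0.0393 TPM and ESRP1 was listed at 0. Of 19 epithelial genes 13 were detected (median 5.29 TPM, or 28.8 TPM over the detected members). Of 19 mesenchymal genes 16 were detected (median 23.1 TPM, or 41.2 TPM over the detected members), led by FN1 at 2696 ± 12.1 TPM and VIM at 2534 ± 49.7 TPM. CDH2, encoding N-cadherin, was at 121.4 ± 5.73 TPM, while TWIST1 and TWIST2 were listed at 0. Among 31 matrix genes 21 were detected (median 17.2 TPM, or 71.2 TPM over the detected members). TGFBI at 2087 ± 9.76 TPM and the collagen VI gene COL6A3 at 637.4 ± 6.12 TPM stood far above the fibrillar collagen gene COL1A1 at 1.19 TPM, and COL1A2 was listed at 0. YAP/TEAD targets were detected for 22 of 23 members (median 46.4 TPM), led by CCN1 at 567.8 ± 11.6 TPM. TGF-β targets were detected for 19 of 20 (median 73.9 TPM), with ID1 at 532.6 ± 2.72 TPM.

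Proliferation genes were expressed throughout. All 25 G1/S and replication genes (median 68.8 TPM) and all 26 G2/M genes (median 106.4 TPM) were detected. TYMS, the thymidylate synthase gene, was at 406.4 ± 14.9 TPM and UBE2C, which acts in mitotic exit, at 457.2 ± 14.4 TPM. MYC targets were detected for 23 of 23 members (median 92.3 TPM), and MYC itself was at 73.9 ± 0.315 TPM. Ribosomal protein genes were detected for 43 of 43 (median 2442 TPM). Of 21 p53 targets 19 were detected (median 14.2 TPM), with CDKN1A at 58.6 ± 1.47 TPM. The cyclin-dependent kinase inhibitor gene CDKN2A and the neighbouring CDKN2B were listed at 0. Immediate early and ERK feedback genes were detected for 23 of 25 members (median 29.6 TPM, or 44.8 TPM over the detected members), with FOSL1 at 259.7 ± 9.17 TPM and DUSP6 at 13.1 ± 1.62 TPM.

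Antigen presentation, interferon-stimulated and NF-κB target genes were mostly detected. All 12 antigen presentation genes were detected (median 206.4 TPM), although reads of similar genes in this list can be divided among them. Of the 31 interferon-stimulated symbols 30 were in the table and 28 were detected (median 13.6 TPM), led by IFITM3 at 508.8 ± 28.6 TPM, while MX1 was at 1.58 ± 0.0403 TPM. NF-κB targets and cytokines were detected for 22 of 26 members (median 33.1 TPM). CXCL8 was at 180.7 ± 19.2 TPM, IL6 at 40.2 ± 3.20 TPM and the adhesion gene VCAM1 at 215.3 ± 14.6 TPM.

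Metabolic and stress genes were mostly detected. Sterol synthesis genes were detected for 22 of 23 members (median 44.5 TPM). Fatty acid and lipid droplet genes were detected for 18 of 20 (median 50.2 TPM), with ACLY at 210.0 ± 1.35 TPM and the carnitine transferase gene CPT1A at 0.851 ± 0.253 TPM. In the ER stress and amino acid list 24 of 25 were detected (median 182.3 TPM). ATF4 was at 804.4 ± 21.9 TPM and PSAT1, the second enzyme of serine synthesis, at 397.2 ± 29.8 TPM, whereas PHGDH, the enzyme before it, was listed at 0 in both libraries. NRF2 targets were detected for 19 of 20 (median 32.5 TPM), with NQO1 at 112.3 ± 2.21 TPM. Heat shock genes were detected for 13 of 15 (median 198.2 TPM), and reads of HSPA1A and HSPA1B, near-identical copies, can be split between them. Of 9 metallothionein and zinc exporter genes 5 were detected (median 12.1 TPM, or 262.6 TPM over the detected members), with MT2A at 5240 ± 20.8 TPM and MT1G listed at 0.

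Around KCNQ1 on 11p15.5, a list fixed without a coordinate for either target site, 14 of 27 genes were detected (median 1.55 TPM, or 28.7 TPM over the detected members). CTSD, the cathepsin D gene, was highest at 2751 ± 77 TPM, followed by CD81 at 411.5 ± 4.80 TPM. PHLDA2 was at 70.2 ± 5.73 TPM and the noncoding KCNQ1OT1 at 2.72 ± 0.145 TPM, while H19 was at 0.166 ± 0.0209 TPM. Counting strand is not given in the sources used here, so KCNQ1OT1 reads cannot be told from those of the overlapping KCNQ1. Of 32 genes listed from general knowledge as at or near reported kidney cancer risk loci, 25 were detected (median 16 TPM). SCARB1 was at 79.2 ± 2.71 TPM, BHLHE41 at 20.3 ± 0.308 TPM and TERT at 4.92 ± 0.407 TPM, and DPF3 was at 0.0662 and 0.199 TPM.

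Markers of other cell types were low, with exceptions. Of 12 endothelial markers 3 were detected (median 0.112 TPM, or 9.40 TPM over the detected members), of which EGFL7 was highest at 34.2 ± 2.49 TPM, and PECAM1 was at 0.160 ± 0.0975 TPM. Of 16 leukocyte markers 4 were detected (median 0.0690 TPM, or 4.80 TPM over the detected members). The leukocyte median was 0.0781 TPM in replicate 1 alone and 0.0192 TPM in replicate 2 alone. CD68, a lysosomal protein gene, was at 81.8 ± 1.87 TPM, whereas PTPRC was listed at 0. Of 12 fibroblast markers 5 were detected (median 0.534 TPM, or 2.28 TPM over the detected members), with LUM at 17.2 ± 2.35 TPM. Of 12 neural markers 4 were detected (median 0.394 TPM, or 37.0 TPM over the detected members), with TUBB3 at 137.6 ± 0.326 TPM and NEFL at 58.9 ± 1.30 TPM. Replication-dependent histones, listed as genes whose transcripts lack poly(A) tails, were detected for 16 of 43 members, led by H2BC12 at 30.5 ± 3.49 TPM. Their median was 1.12 TPM, or 2.89 TPM over the detected members. Whether the transcripts measured here lack such tails was not tested.

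**Figure D1:**
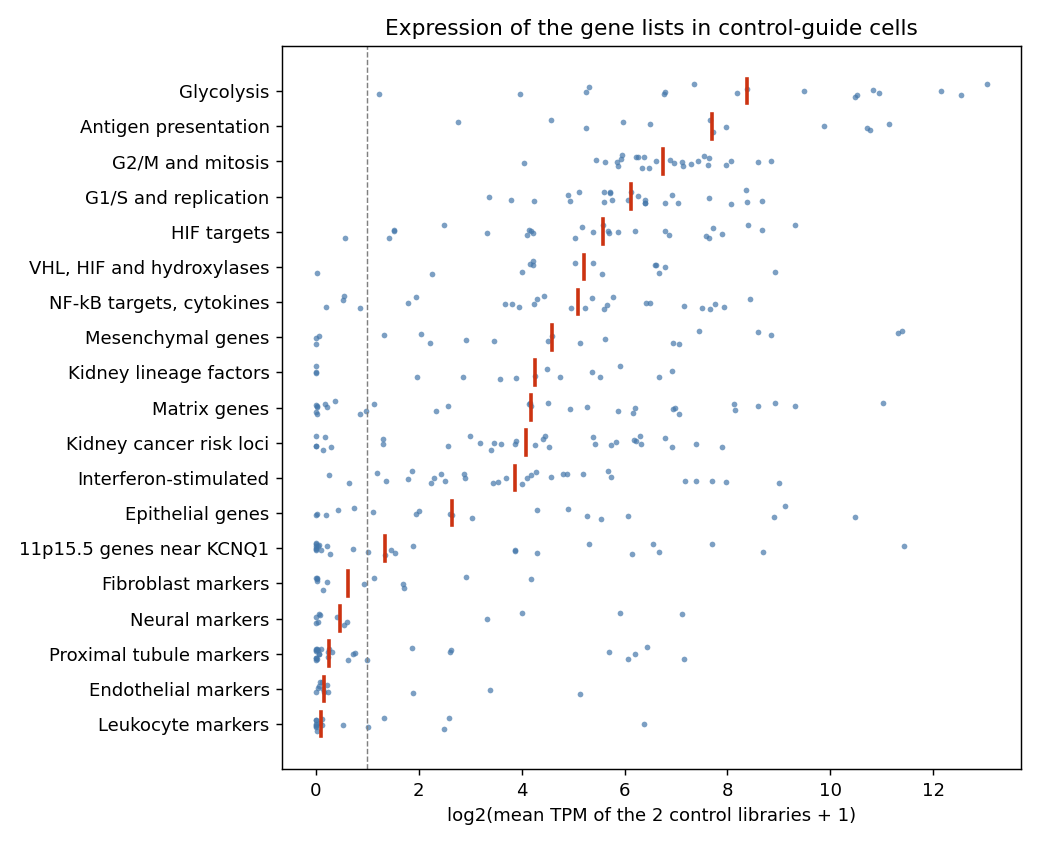
Each point is a gene, placed by log2(mean TPM + 1) over the 2 control libraries on the x axis, grouped by gene list (some of the lists) on the y axis with vertical jitter; red bars are list medians and the dashed line marks 1 TPM. Glycolytic genes have the highest median shown (333.2 TPM) and leukocyte markers the lowest (0.0690 TPM over both libraries, 0.0781 and 0.0192 TPM in each alone).

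The 2 control libraries were close to each other in the list genes with a mean estimated count of at least 50. Across genes, which are not independent replicates, log2(TPM + 1) correlated at Pearson r = 0.992 and TPM at Spearman rho = 0.967. Among 12404 genes with a mean estimated count of at least 50, the median absolute log2 ratio between libraries was 0.09, and 36 genes (0.290%) were 2-fold or more apart. This number was 133 with a mean estimated count of at least 10 and 9 with at least 200. None of the 543 list genes compared was 2-fold apart; the largest gap among them was 0.79 on the log2 scale, for S100A4. In 29 lists with at least 5 genes compared, the list median of the log2 ratio of replicate 2 over replicate 1 ran from -0.07 to 0.06.

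The genes that were apart were mostly small noncoding RNAs, read-through symbols and near-identical copies. Of 22 small nucleolar RNAs (snoRNAs, which guide the modification of ribosomal RNA) compared, 17 were 2-fold apart, as were both 7SL RNA genes, which encode the RNA of the signal recognition particle, 5 of 58 read-through symbols and 6 of 6 genes in 3 sets of near-identical copies chosen after their values were seen. Of the 12316 other genes 6 were 2-fold apart: IQCH-AS1, GTF2IRD2, L1TD1, ZNF506, TSGA10 and PIGY, whose annotated span is the same as that of PYURF. RN7SL2 was at 1918 TPM in replicate 1 and 17602 TPM in replicate 2, and RN7SL1 at 935.4 and 9662 TPM. SNORA48 was at 4.61 and 238.2 TPM, while SNORA18 was at 433.5 and 41.6 TPM. The splicing factor gene U2AF1 was at 48.9 and 188.3 TPM while its copy U2AF1L5 was at 263.8 and 90.4 TPM.

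**Figure D2:**
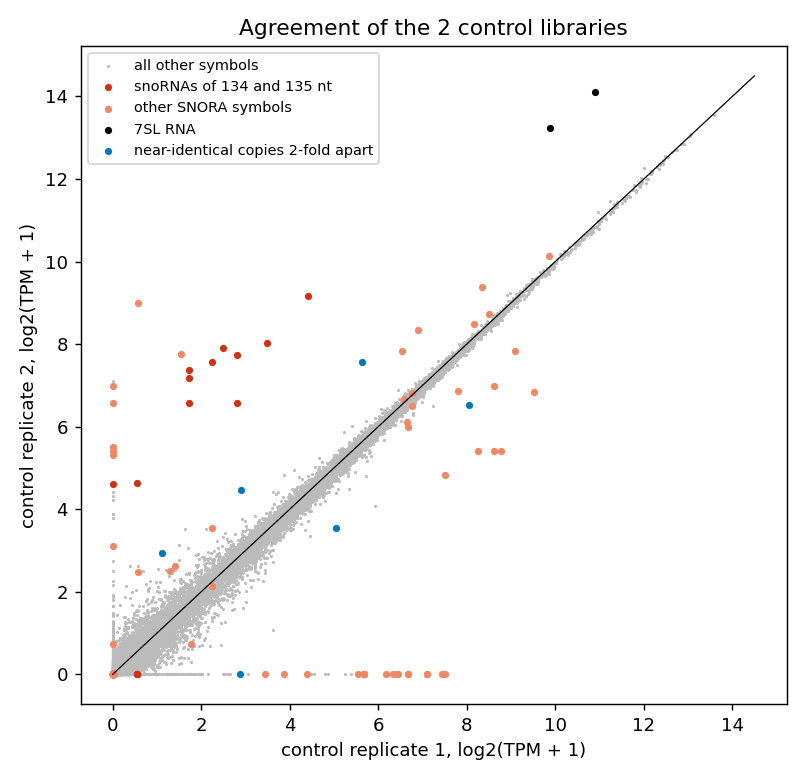
Each point is a gene symbol, with log2(TPM + 1) in control replicate 1 on the x axis and control replicate 2 on the y axis; the line marks equal values and colours mark small nucleolar RNAs, 7SL RNA and near-identical copies 2-fold apart. Most symbols lie along the line (r = 0.992). The coloured symbols include the 17 snoRNAs, 2 genes of 7SL RNA and 6 near-identical copies that were 2-fold apart in CPM at a mean estimated count of at least 50. Read-through symbols and other genes that were apart are not coloured, and symbols at lower counts were not counted by class.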

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

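All alternatives reported here were chosen after the data were seen. The 77 planned ones concern the comparisons with targeted cells and were not run. No paired analysis was possible because the columns used carry 1 group only, so no replicate number is shared between groups. The number of genes detected in both control libraries was 13023 and stayed within 1.5 times that number at 0.5 TPM (13969), at 5 TPM (10177), at 1 CPM (13137) and in either library alone (13361 to 13405). The 36 genes 2-fold apart became 133 with a mean estimated count of at least 10 and 9 with at least 200, and 6 without snoRNAs, 7SL RNA, read-through symbols and near-identical copies; scaling by the median ratio of genes left the number at 36. The correlation of the libraries, 0.992, became 0.985 with log2(TPM + 0.1) and 0.998 with log2(CPM + 1), both beyond the tolerance of 0.005; the cause was not tested. It was 0.992 over genes at 1 TPM or more in both. Of the 113 alternatives for list medians and single genes, 78 moved the value by no more than the SD between the libraries and 35 by more. Leaving out a library keeps a single gene within that SD by construction. The same holds for a list whose median falls on the same gene in both libraries, such as glycolysis. Leaving out members under 1 TPM changes nothing in a list that has none. Such cases among the 78 are no evidence of stability. Of the 35, 21 left out list members under 1 TPM, which by construction raises a median. With 2 libraries of 1 group, the SD itself is uncertain, and the depth in reads behind single values is unknown because the deposited counts are proportional to TPM within each gene.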

Other observations

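By the mean over the 2 control libraries, TMSB10, encoding thymosin β10, had the highest TPM at 12163 ± 202.0 (SD, n = 2), although RN7SL2 was above it in replicate 2 at 17602 TPM. It was followed among protein-coding genes by RPS2 at 8695 ± 89.5 TPM, GAPDH at 8434 ± 4.23 TPM and the ferritin heavy chain gene FTH1 at 7501 ± 199.4 TPM. LGALS1, encoding galectin-1, was at 6370 ± 35.8 TPM, and S100A6 at 4054 ± 170.2 TPM.

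Of the tests on the differences between the control libraries, those on snoRNAs, on near-identical copies and on carry-over with 7SL RNA were chosen after the result, or part of the values they use, had been seen. The test on genes of the length of 7SL RNA was chosen before. The sets of copies and the other lengths of snoRNA were also picked because they differed between the libraries. The lengths of 134 and 135 nt were picked because their TPM steps, described below, differed by at least 10-fold. That difference in steps is therefore no separate evidence, whereas the multiples of the steps were not used for the pick. The labels put both libraries in 1 group, so no biological explanation was tested. Carry-over of non-polyadenylated RNA presupposes that polyadenylated RNA was selected, and the selection of RNA is not reported here.

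snoRNAs of 134 and 135 nt were much higher in TPM in replicate 2, by a median log2 ratio of 5.50 over 10 genes above 0 in both libraries. Within each of these lengths, the TPM values of a library were whole multiples of 1 step within 0.02: the step was 0.465 TPM in replicate 1 and 23.5 TPM in replicate 2 at 134 nt, and 0.461 and 23.8 TPM at 135 nt. SNORA48 was at 10 steps in both libraries (4.61 and 238.2 TPM) and SNORA25 at 8 steps in both (3.72 and 187.7 TPM), and the median log2 ratio of the multiples was -0.16 against -0.49 for the ratio of library totals. Other genes differed in steps, with SNORA16A at 13 and 4, SNORA70 at 44 and 24, and SNORA52 at 5 and 7. The multiples summed to 45 and 33 at 134 nt and to 84 and 52 at 135 nt. If a step is 1 fragment, these values are consistent with an effective transcript length that was set very differently in the 2 libraries for similar numbers of fragments. For these lengths, carry-over of more non-polyadenylated RNA in replicate 2 is argued against by the multiples, if a step is 1 fragment. Carry-over was predicted to give snoRNAs of other lengths a median log2 TPM ratio over 1, replicate 2 over replicate 1. Their median was 0.058 (standard error 0.71, n = 27). That spread is wide, and some of these lengths hold further snoRNAs far apart in both directions, so this median cannot decide the question.

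Of the 17 snoRNAs 2-fold apart, 6 were of these lengths. At 132 nt 4 were apart, each higher in replicate 1, while the steps were 43.3 and 41.6 TPM, a log2 ratio of -0.55 once the library totals are taken out, against at least 1.41 for the genes in absolute value. This argues against a different effective length as the whole cause there, where SNORA18 was at 10 steps and 1 step. SNORA69 and SNORA41, not among those apart, went the other way, at 0 and 3 steps and at 0 and 1. Over all 8 symbols of 132 nt the multiples summed to 41 and 10, a ratio of 0.244 against 0.712 for the library totals. The multiples of single genes are few at this length too. At 133 nt 5 were apart, with steps of 45.6 and 28.3 TPM, a log2 ratio of -1.17 once the library totals are taken out, and multiples of 12 and 8 in SNORA9, 16 and 4 in SNORA33, 3 and 0 in SNORA21 and SNORA68, and 2 and 8 in SNORA66. SNORA10 was not apart, at 8 and 15 multiples, and over all 8 symbols of this length the multiples summed to 49 and 35, a ratio of 0.714 against 0.712 for the library totals. A different effective length goes in the direction of 4 of the 5 and against SNORA66, and cannot be told apart from a change in single RNAs, since the multiples of single genes are few. At 137 nt, where no snoRNA was among those apart, the steps were 35.7 and 44.7 TPM. The multiples there summed to 48 and 51, a ratio of 1.06 against 0.712 for the library totals. SNORA3B and SNORA24, both of 131 nt and too few there for a step to be found, were at 0.475 and 507.4 TPM and at 1.90 and 217.5 TPM.

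The estimated counts carry the same differences, since they are proportional to TPM within each gene. SNORA18 had 10 steps in replicate 1 and 1 step in replicate 2, but estimated counts of 217.6 and 15.3, and SNORA48 had 10 steps in both but counts of 3.77 and 141.9.

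7SL RNA was 9.32-fold (RN7SL2) and 10.4-fold (RN7SL1) higher in replicate 2 in CPM, and took 0.286% of all TPM in replicate 1 and 2.74% in replicate 2. The summed TPM of all genes but 7SL RNA and SNORA genes differed by -0.04 on the log2 scale, replicate 2 over replicate 1. More carry-over of non-polyadenylated RNA as a whole was predicted to give other such RNAs a median log2 ratio over 1. In 26 RNAs taken as such, mostly histones at low levels, the median was 0.080 (standard error 0.26). Whether the histone transcripts measured here lack poly(A) tails was not tested, so this median cannot decide the question. Among members other than histones, RN7SK was at 10.8 and 6.97 TPM, SCARNA2 at 1.89 and 1.35 TPM and RPPH1 at 2.70 and 6.44 TPM. SNORA73A was at 107.1 and 111.5 TPM, and SNORA73B at 95.5 and 100.7 TPM. RNA18SN4, outside this set, was at 4105 and 4960 TPM. None of these rose as much as 7SL RNA. The test on length found 0 other genes with a genomic span of 280 to 320 nt and a mean of 1 TPM or more. A genomic span includes introns, so this choice left out spliced transcripts of that length, which were not compared. The test therefore cannot tell a different effective length in each library from a change in 7SL RNA itself.

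In 3 sets of near-identical copies, picked because their members were apart, the members moved in opposite directions between the libraries and their sums differed by less. The summed TPM of U2AF1 and U2AF1L5 was 312.6 and 278.7, and the largest absolute log2 ratio of a sum over the 3 sets was 0.28, for SERF1A and SERF1B, against up to 3.77 for a single member with a pseudocount of 0.5 TPM. The values go with reads shared between these copies being divided differently in each library, so a call on U2AF1 alone may rest on that division.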
